A study of Mus musculus with 16 samples.

How the data were processed

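RNA was measured by sequencing in 16 mouse liver samples of the C57BL/6J strain, in 4 groups of 4 libraries: wild type and hepatic Tsc1 knockout, each on a control diet or under the Gao-binge alcohol regimen, with a time of 10 days given for every sample. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, polyA RNA was selected from Trizol-extracted total RNA, libraries were made with a NEBNext stranded mRNA kit, and single reads of 75 bp were read on a NextSeq instrument. The labels do not say whether the libraries of a group came from separate animals, so all p-values measure the spread between these libraries, which may in part be technical.

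The authors deposited a table of raw read counts per gene. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with HISAT2 2.1.0 and counted with HTSeq, and the genome build was GRCm38. The HTSeq version, its strand and multiple-mapping options and the annotation release are not given in the sources used here. The kit marks the strand, so a wrong strand setting would lower counts and mix overlapping antisense genes, and reads shared by near-identical genes could be lost or split. Values of the Cyp2a, Cyp2b, Cyp2c, Ces, Gst, Mup, Ugt2b, Slc22a and ribosomal protein families are therefore uncertain in how they divide among family members. Of 200 named genes, 199 were placed uniquely in the GENCODE M21 annotation of GRCm38, which need not be the release the authors used. Exons of 16 overlapped another gene on the same strand and exons of 44 overlapped one on the other strand.

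The count table held 55487 rows, of which 7436 had no gene symbol. Those rows held 0.226 to 0.479% of the counts of a library and were left out of library sizes and tests. Another 86 rows repeated a symbol and were kept apart, and 24 symbols had the form of a date, so the genes behind them were not named. Total counts per library ran from 14.75 to 21.757 M. Intervals given for single counts cover counting error only, since reads without molecular identifiers are not independent molecules.

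The authors also deposited a table of their own 4 pairwise comparisons, with log2 fold changes and with adjusted p-values under the column names that DESeq2 writes, per the file headers. The base mean was identical in all 4 comparisons in 27992 of 27992 genes, as in 1 fit of all libraries. Its log2 fold changes are signed the other way, as control over ethanol and wild type over knockout. Only its counts of genes with an adjusted p-value under 0.05 were used, for a comparison of totals.

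Tests were run on the deposited counts in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups, which left 14346 genes, libraries were scaled by TMM factors, and 1 quasi-likelihood model with a mean for each group was fitted to all 16 libraries (glmQLFit and glmQLFTest, robust, 12 residual degrees of freedom, biological coefficient of variation 0.205). The labels state no test, so this design was fixed before the data were examined. The 5 contrasts were Tsc1 loss on control diet, Tsc1 loss after ethanol, ethanol in wild type, ethanol in knockout, and the interaction, which is the difference between the 2 ethanol effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a single gene is from this test. Log2 fold changes are given with their standard errors. CPM values are counts scaled to the TMM-adjusted library size, given with the SD over 4 libraries. Exact two-sided permutation tests on log2 CPM were run for Tsc1 alone. The smallest p such a test can give with 4 libraries against 4 is 0.0286.

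Before the data were examined, 49 gene lists were written down from textbook knowledge, with 1123 distinct members. The symbol of 1115 matched the table directly, 6 matched by a synonym and 2 did not match. With at least 5 tested members, 46 lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. With an estimated correlation, 0 of the 46 lists passed in each of the 5 contrasts, and 2, 2, 3, 3 and 1 had an unadjusted p under 0.05. Fry called 11, 21, 20, 11 and 0 lists in the order of the contrasts above. A list's score in a library is the median over its members of the log2 difference from the mean of the wild-type controls. A list of glucocorticoid receptor targets was added after the data were examined.

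Genes were named by a rule fixed before the data were examined. It took Tsc1 everywhere; the 8 largest rises and falls of each pairwise contrast among called genes with a mean CPM of at least 2, no overlap between the groups and a symbol that is not a clone or predicted name; up to 4 called list members with the smallest p and up to 2 uncalled members with the highest level; and the 8 smallest p of the interaction. The text gives some of these and summarises the others. Results of 3 genes that the rule named are not reported here. Members may be named again to set another contrast beside them.

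The gene test and the list tests were tested on simulated counts drawn from the real means and library sizes with 200 changed genes. The recovered share ranged over the 5 contrasts from 7.7 to 27.3% at 1.5-fold, from 41.5 to 62.1% at 2-fold and from 78.5 to 89.4% at 4-fold. These shares hold for 200 changed genes. The real pairwise contrasts called 1766 to 5551 genes, so their adjusted threshold was looser and the shares set no limit for them. Of 5551 genes called for Tsc1 loss after ethanol, 1961 changed at least 2-fold. All pairs of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 15.9 or more, so each library was counted once.

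The alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, only the 2 groups compared, and leaving out each library in turn. A fit without knockout ethanol libraries 1 and 2 was added after the data were examined, because these 2 stood apart from their group. Gene positions, tables and plots were made with Python, pandas and matplotlib.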

Results

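Gene expression was measured by polyA RNA sequencing in 16 liver libraries of C57BL/6J mice. Tsc1 encodes a subunit of the complex that restrains the growth-controlling kinase mTORC1. The libraries formed 4 groups of 4, namely wild type and hepatic Tsc1 knockout on a control diet, and both genotypes under the Gao-binge regimen, which joins chronic feeding of an alcohol diet with a final alcohol gavage. The design asks what hepatic loss of Tsc1 changes, what alcohol (called ethanol here) changes, and whether the alcohol response differs between genotypes. Total read counts were 17.8 ± 0.894 M (SD, n = 4) in wild-type controls, 19.5 ± 1.84 M in wild type after ethanol, 16.7 ± 0.974 M in knockout controls and 16.3 ± 1.31 M in knockout after ethanol. The range over single libraries was 14.75 to 21.757 M.

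Albumin transcripts, the main secreted product of hepatocytes, took 7.97 ± 0.291% (SD, n = 4) of counts in wild-type controls and 8.34 ± 0.450% in wild type after ethanol. In the knockout they took 3.70 ± 0.341% on control diet and 4.84 ± 1.5% after ethanol. Mitochondrially encoded transcripts took 3.78 ± 0.304% and 5.45 ± 0.316% of counts in wild type on control diet and after ethanol, and 5.13 ± 0.456% and 7.78 ± 1.72% in the knockout. The first 2 principal components of log2 CPM held 33.2% and 29.4% of the variance. The 4 groups lay apart on them, and knockout ethanol library 2 lay farthest from its group.

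**Figure D1:**
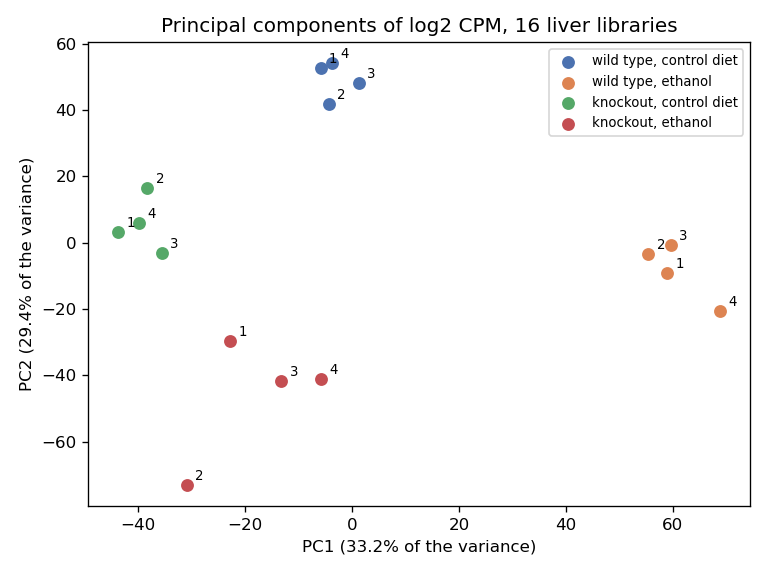
Principal components 1 and 2 of log2 CPM, 1 point per library with its replicate number, coloured by group. The axes hold 33.2% and 29.4% of the variance, and knockout ethanol library 2 lies at -73.0 on the vertical axis against -29.5 to -41.7 for the other 3 of its group.

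Tsc1 itself (chromosome 2, 28641228 to 28691167 on the plus strand of GRCm38) was counted at 26.6 ± 2.52 CPM (SD, n = 4) in wild-type controls and 18.5 ± 3.29 CPM in knockout controls, which is 69.6% of the wild-type level. After ethanol it stood at 18.4 ± 1.77 CPM in wild type and 14.3 ± 1.93 CPM in the knockout, or 77.7%. The fall with Tsc1 loss was -0.52 ± 0.13 log2 on control diet (SE, adjusted p = 0.0147; exact permutation p = 0.0286, the smallest possible) and -0.36 ± 0.13 after ethanol (adjusted p = 0.0386; exact permutation p = 0.0571). Ethanol lowered Tsc1 in wild type by a similar amount, -0.53 ± 0.13 log2 (adjusted p = 0.00487), and the value in the knockout was -0.37 ± 0.13 (adjusted p = 0.0686). The interaction was 0.16 ± 0.19 log2 (adjusted p = 0.680). The labels do not say which exon was removed, and reads from the rest of the transcript and from cells other than hepatocytes are counted too, so the level checks the genotype labels only in part. The call on control diet was lost without wild-type control library 4 (-0.46) or knockout control library 3 (-0.47). After ethanol it was lost without wild-type control library 1, 3 or 4 (-0.35 each), wild-type ethanol library 1 (-0.34), 2 (-0.32) or 3 (-0.34), or knockout ethanol library 1 (-0.28), 2 (-0.38) or 3 (-0.34).

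Loss of Tsc1 on control diet changed 1766 of 14346 genes, 1061 upward and 705 downward. The largest rises were in the matrix metalloproteinase Mmp7 (6.15 ± 0.72 log2, SE, adjusted p = 1.07e-04), the secreted antioxidant enzyme Gpx3 (5.71 ± 0.55) and the collagen gene Col5a2 (5.39 ± 0.28, adjusted p = 1.08e-08). Mmp27, Slc35f2, Epdr1, Rragd and Cyp46a1 rose by 3.88 to 4.96 log2. The largest fall was in Slc22a7, an organic anion transporter of hepatocytes, at -5.08 ± 0.37 log2 (adjusted p = 9.91e-07), from 50.9 ± 9.79 to 1.52 ± 0.888 CPM (SD, n = 4). Dct, Slc17a8, Serpina7, Hectd2os, Nat8, Slc22a28 and the acyl-CoA thioesterase Acot3 fell, at -4.25 to -2.85 log2. Hectd2os is an antisense transcript, and its reads cannot be told from those of its partner without the counting strand. The call of Acot3 was lost without wild-type control library 1 (-2.57) or 3 (-2.52) and without knockout control library 2 (-2.77), 3 (-2.87) or 4 (-2.50), and with no filter (adjusted p = 0.0667). The authors' deposited table had 2193 genes with an adjusted p-value under 0.05 for this comparison. On the same counts DESeq2 called 2160 and voom 3603.

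Genes of the lysosome rose together. Of 38 tested members of the TFEB target network, the set that a master regulator of lysosomes activates, 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.45 log2 (camera adjusted p = 1.18e-12, or 0.0993 with an estimated correlation). The Rag GTPase gene Rragd (chromosome 4, 32983037 to 33022180, plus strand) rose from 1.84 ± 0.350 to 35.4 ± 5.37 CPM (SD, n = 4), 19.1-fold. Hexa and the protease gene Ctsz rose by 1.15 and 1.00 log2. Of 17 mTORC1 pathway components, Tsc1 among them, 3 rose and 2 fell (5 and 2 over the list alone; camera adjusted p = 0.160, or 0.381 with an estimated correlation), and the stress-responsive Sesn3 rose by 1.49 log2. Voom called 6 of these higher.

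Cytosolic ribosomal protein transcripts fell. Of 73 tested, 46 fell and 0 rose (58 and 0 adjusted over the list alone), with a median of -0.53 log2 (camera adjusted p = 5.82e-26, or 0.381 with an estimated correlation). Rpl30 (chromosome 15, 34440505 to 34443640, minus strand) fell from 33.4 ± 3.17 to 16.8 ± 0.877 CPM (SD, n = 4), and Rps25 fell by 0.82 log2. In the list of ribosome biogenesis factors and MYC targets, 9 of 31 fell and 0 rose (12 and 0 over the list alone; adjusted p = 1.06e-06, or 0.381 with an estimated correlation), among them the nucleolar genes Nolc1 (-0.47) and Npm1 (-0.64). Of 56 nuclear genes of oxidative phosphorylation, 8 fell and 0 rose (10 and 0 over the list alone; adjusted p = 1.62e-07, or 0.709 with an estimated correlation), with Ndufa8 at -0.69. Voom called more falls, 18 in the ribosome biogenesis list and 22 in oxidative phosphorylation, and DESeq2 called 11 in each.

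Genes of fat handling fell on the control diet. In fatty acid oxidation and ketogenesis 12 of 29 members fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 9.95e-08, or 0.381 with an estimated correlation), including the thiolase gene Acaa2 (-0.71 ± 0.13). Fabp1 was at -0.50 ± 0.26 log2 (adjusted p = 0.237). In de novo lipogenesis 6 of 18 fell and 1 rose (7 and 1 over the list alone; adjusted p = 8.42e-04, or 0.709 with an estimated correlation). Malic enzyme Me1 fell by 1.88 log2 and the lipase gene Pnpla3 by 3.00, and voom called 10 falls in this list, while the desaturase Scd1 was at -0.59 ± 0.46 (adjusted p = 0.454). The call of Pnpla3 was lost without wild-type control library 1 (-3.12) or 4 (-2.19), wild-type ethanol library 2 (-3.00), or knockout control library 1 (-2.62), 2 (-2.63) or 3 (-3.05). It was lost too with no filter (adjusted p = 0.0771) and with the replicate block (0.06). The hepatocyte identity list had 4 of 23 members lower and 0 higher (4 and 0 over the list alone; adjusted p = 0.0239, or 0.709 with an estimated correlation). Alb (chromosome 5, 90460897 to 90476602, plus strand) was the most abundant, at 34470 ± 2717 CPM against 80640 ± 4326 (SD, n = 4). The call of that list (median -0.178 log2, -0.106 without wild-type control library 1) was lost without wild-type control library 3 (median -0.166, adjusted p = 0.0602) or knockout control library 1 (-0.169, adjusted p = 0.0526).

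Cholangiocyte and fetal liver markers rose. Of 20 cholangiocyte and ductular reaction markers, 13 rose and 0 fell (15 and 0 adjusted over the list alone, median 1.73 log2; camera adjusted p = 1.40e-08, or 0.381 with an estimated correlation). The secreted matrix protein gene Spp1 rose by 2.62 ± 0.42, the tight junction gene Cldn4 by 2.97 ± 0.57 and the surface marker Cd24a by 2.23 ± 0.43, while Krt8, also a keratin of hepatocytes, was at -0.32 ± 0.27 (adjusted p = 0.496). Of 17 fetal liver and hepatocellular tumour markers, 5 rose and 0 fell (9 and 0 over the list alone; adjusted p = 3.20e-07, or 0.381 with an estimated correlation), with Bex2 and Bex1 up by 4.36 and 3.09 log2, and DESeq2 called 9 and voom 10 of these. Of 21 chemokines and cytokines 5 rose and 0 fell (6 and 0 over the list alone; adjusted p = 0.00692, or 0.381 with an estimated correlation), Cx3cl1 among them (1.46). Of 21 monocyte and macrophage markers edgeR called 1, Cd68 at 0.98 ± 0.31, where DESeq2 called 2 and voom 10 higher (0 over the list alone; adjusted p = 0.00692 for the list, or 0.709 with an estimated correlation). The call of Cd68 was lost without wild-type control library 1 (0.91), 3 (0.87) or 4 (0.87), wild-type ethanol library 2 or 4 (0.99 each), knockout control library 1 (1.02), 2 (0.98) or 4 (0.77), or knockout ethanol library 4 (0.99), with no filter (adjusted p = 0.117) and with only the 2 groups compared (0.0512), and that of its list without wild-type control library 3 (adjusted p = 0.0611). The median of the list was 0.586 log2, 0.392 in that fit, 0.889 without wild-type control library 2 and 0.358 without knockout control library 4.

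Stress genes rose as well. Of 32 targets of ATF4, the transcription factor of the amino acid stress response, 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.00227, or 0.709 with an estimated correlation). The mTORC1 inhibitor gene Ddit4 rose by 2.26 ± 0.30 log2, Nupr1 by 3.34 ± 0.53 and the stress hormone gene Gdf15 by 3.62 ± 0.67. Of 23 p53 targets and growth arrest genes 6 rose and 0 fell (10 and 1 over the list alone; adjusted p = 8.06e-04, or 0.381 with an estimated correlation), with Eda2r up by 3.67 ± 0.51 and the pro-apoptotic Bax by 0.79 ± 0.14. The count of 1766 genes fell to between 1091 and 1140 without wild-type control library 1 (1137) or 4 (1135) or knockout control library 1 (1131), 3 (1140) or 4 (1091).

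**Figure D2:**
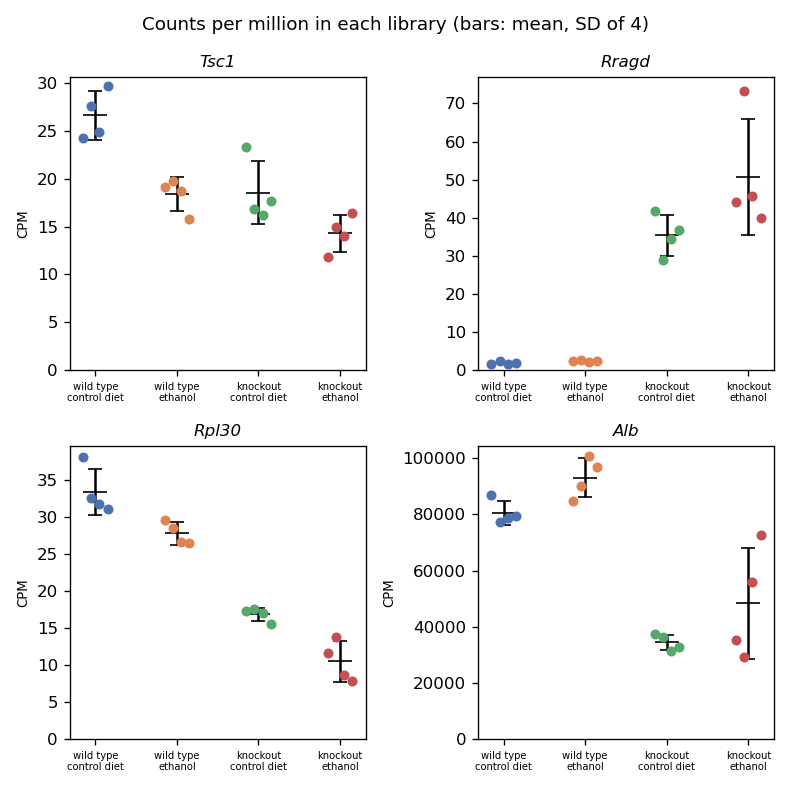
Tsc1, Rragd, Rpl30 and Alb in CPM in each of the 16 libraries by group, with bars for the mean and SD of 4. Rragd stands at 28.9 to 73.3 CPM in the 8 knockout libraries and 1.56 to 2.63 in the 8 wild-type libraries, while Tsc1 stands at 24.3 to 29.7 CPM in wild-type and 16.2 to 23.4 in knockout controls.

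After ethanol, 5551 genes differed between knockout and wild type, 2811 higher and 2740 lower in the knockout. Mmp7, Gpx3 and Col5a2 were again among the largest rises, at 6.86 ± 0.69, 6.33 ± 0.56 and 5.69 ± 0.29 log2 (SE, adjusted p = 6.41e-09 for Col5a2), and Slc22a7 was again the largest fall (-5.01 ± 0.38). The fetal non-coding RNA H19 (chromosome 7, 142575529 to 142578143, minus strand) had 12537 counts in the knockout against 3 in wild type, a depth-scaled ratio of 4356 with a 95% counting interval of 1490 to 21130. Most of these counts came from knockout ethanol library 2, at 675.2 CPM against 4.06 to 17.4 in the other 3. Cfap44 had 357 counts against 2, a ratio of 186.1 (51.1 to 1542). Ubd, Sprr1a and Clec2h rose by 5.06 to 5.31 log2, and without knockout ethanol library 2 the value of Ubd was 3.38 and the call of Sprr1a was lost (3.16). Without wild-type ethanol library 1 the fitted value of Sprr1a was 9.10. Hsd3b5, a male-biased steroid enzyme of mouse liver, Il1r1, the receptor of interleukin 1, and Scara5, Nat8, Serpina12, Slc10a2 and Ttll11 fell, at -4.25 to -3.16 log2. Without knockout ethanol library 1 the value of Hsd3b5 was -6.89. The authors' deposited table had 5849 genes with an adjusted p-value under 0.05 here, and DESeq2 run on the same counts called 5829.

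The lysosomal rise and the ribosomal fall were also present after ethanol. Of 38 TFEB targets 24 rose and 3 fell (25 and 3 adjusted over the list alone, median 0.52 log2; camera adjusted p = 2.01e-08, or 0.375 with an estimated correlation). Rragd rose 21.7-fold, from 2.33 ± 0.257 to 50.7 ± 15.3 CPM (SD, n = 4), and the sialidase gene Neu1 by 1.25 log2. Of 73 ribosomal protein transcripts 54 fell and 0 rose (58 and 1 over the list alone, median -0.67; adjusted p = 2.82e-17, or 0.620 with an estimated correlation), with Rpl30 at -1.41 ± 0.14 and Rps3a1 at -1.34 ± 0.14. Of 31 ribosome biogenesis and MYC target genes 22 fell and 0 rose (23 and 0 over the list alone; adjusted p = 1.57e-06, or 0.620 with an estimated correlation), Nop58 (-1.47) and Wdr43 (-0.87) among them.

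Immune and interferon genes were higher in the knockout after ethanol. Of 37 interferon-stimulated genes 28 rose and 0 fell (31 and 0 adjusted over the list alone, median 1.49 log2; camera adjusted p = 2.06e-07, or 0.650 with an estimated correlation). The antiviral genes Oas3, Oas2 and Oasl2 rose by 3.39 ± 0.53, 2.04 ± 0.34 and 2.28 ± 0.43, and Stat2 was at 0.67 ± 0.29 (adjusted p = 0.0767), called without knockout control library 3 (0.67) and by DESeq2 (adjusted p = 0.0498). DESeq2 called 27 of these genes higher and voom with sample quality weights 13. Knockout ethanol library 1 had an interferon score of 2.11 against -0.11 to -0.10 in the other 3 of its group, and without it the list median was 0.59 and Oasl2 was at 1.46. Of 21 monocyte and macrophage markers 17 rose and 0 fell (18 and 0 over the list alone, median 2.29; adjusted p = 5.12e-07, or 0.620 with an estimated correlation). The macrophage glycoprotein gene Cd68 (chromosome 11, 69664213 to 69666153, minus strand) stood at 21.8 ± 6.34 CPM in the knockout and 4.43 ± 1.31 in wild type (SD, n = 4), and lysozyme Lyz2 and the chemokine receptor Ccr2 rose by 2.37 and 2.44 log2. Of 14 Kupffer cell markers 10 rose and 1 fell (10 and 1 over the list alone; adjusted p = 0.00234, or 0.628 with an estimated correlation), with Vsig4 up by 1.61 and Folr2 by 2.32. Without knockout ethanol library 2 the median of the monocyte list was 1.29, and without libraries 1 and 2 of that group it was 1.39 and that of the Kupffer list 0.60. Part of each gap lay in wild type after ethanol, where the mean scores were -0.78 (interferon), -0.90 (monocyte) and -0.82 (Kupffer). In knockout controls they were 0.06, 0.65 and 0.26, and in the knockout after ethanol 0.45, 0.77 and 0.17. Ethanol in the knockout called 1 of 37 interferon genes higher and 1 lower. Of the monocyte markers it called 3 higher and 0 lower, and of the Kupffer markers 0 and 1.

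Growth and fetal genes were higher too. Of 33 cell cycle genes 21 rose and 1 fell (22 and 1 adjusted over the list alone, median 1.29 log2; camera adjusted p = 1.57e-06, or 0.620 with an estimated correlation). Mki67, a marker of dividing cells (chromosome 7, 135689784 to 135716361, minus strand), stood at 7.37 ± 4.43 CPM against 1.47 ± 0.494 (SD, n = 4), Cdk1 and E2f1 rose by 1.77 and 1.51 log2, and Ccnd1 was at 0.49 ± 0.27 (adjusted p = 0.163). Of 17 fetal liver and tumour markers 14 rose and 0 fell (14 and 1 over the list alone, median 2.59; adjusted p = 2.11e-05, or 0.620 with an estimated correlation), with Bex2 at 5.46 ± 0.81 and the lipase gene Lpl at 2.26 ± 0.34. Of 20 cholangiocyte markers 16 rose and 0 fell (16 and 0 over the list alone; adjusted p = 2.94e-07, or 0.620 with an estimated correlation), Epcam by 2.78 and Spp1 by 3.70, while Krt18 was at -0.51 ± 0.25 (adjusted p = 0.115), called without wild-type ethanol library 3 (-0.70). Knockout ethanol library 2 had the highest scores for the fetal list (3.88 against 1.26 to 1.63 in the other 3), the cell cycle list (1.25 against 0.44 to 0.55) and the monocyte list (2.02 against 0.03 to 0.75). Without it the median of the fetal list was 1.65. Without knockout ethanol libraries 1 and 2 the list medians were 0.73 for the cell cycle, 1.60 for the fetal markers and 1.67 for the cholangiocyte markers, each still called by camera, and Epcam was at 1.72.

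Lists of fat and drug metabolism had more members lower than higher in the knockout after ethanol. In fatty acid oxidation and ketogenesis 17 of 29 fell and 0 rose (18 and 0 adjusted over the list alone; camera adjusted p = 1.10e-05, or 0.620 with an estimated correlation), with Acadvl at -0.81 ± 0.11. Of 12 lipid droplet proteins 6 fell and 1 rose (6 and 1 over the list alone; adjusted p = 0.0117, or 0.620 with an estimated correlation). Cidec, a droplet fusion protein, was at -2.15 ± 0.39, Plin5 at -1.64 ± 0.29 and Hilpda at -2.23 ± 0.28, and G0s2 at -0.89 ± 0.44 (adjusted p = 0.122). Of 18 drug-metabolising P450 genes and partners 7 fell and 2 rose (7 and 2 over the list alone; adjusted p = 0.0117, or 0.650 with an estimated correlation), led by the reductase gene Por (-1.5) and the carboxylesterase gene Ces2a (-2.34). Of 23 pericentral hepatocyte genes 9 fell and 1 rose (9 and 1 over the list alone; adjusted p = 0.0117, or 0.751 with an estimated correlation), Notum (-1.29) and Oat (-1.61) among them. The lipid droplet call was lost without knockout ethanol libraries 1 and 2 (median -0.624 log2 against -0.836 with all, adjusted p = 0.0919) and the pericentral call without wild-type ethanol library 3 (-0.297 against -0.516, adjusted p = 0.0803).

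**Figure D3:**
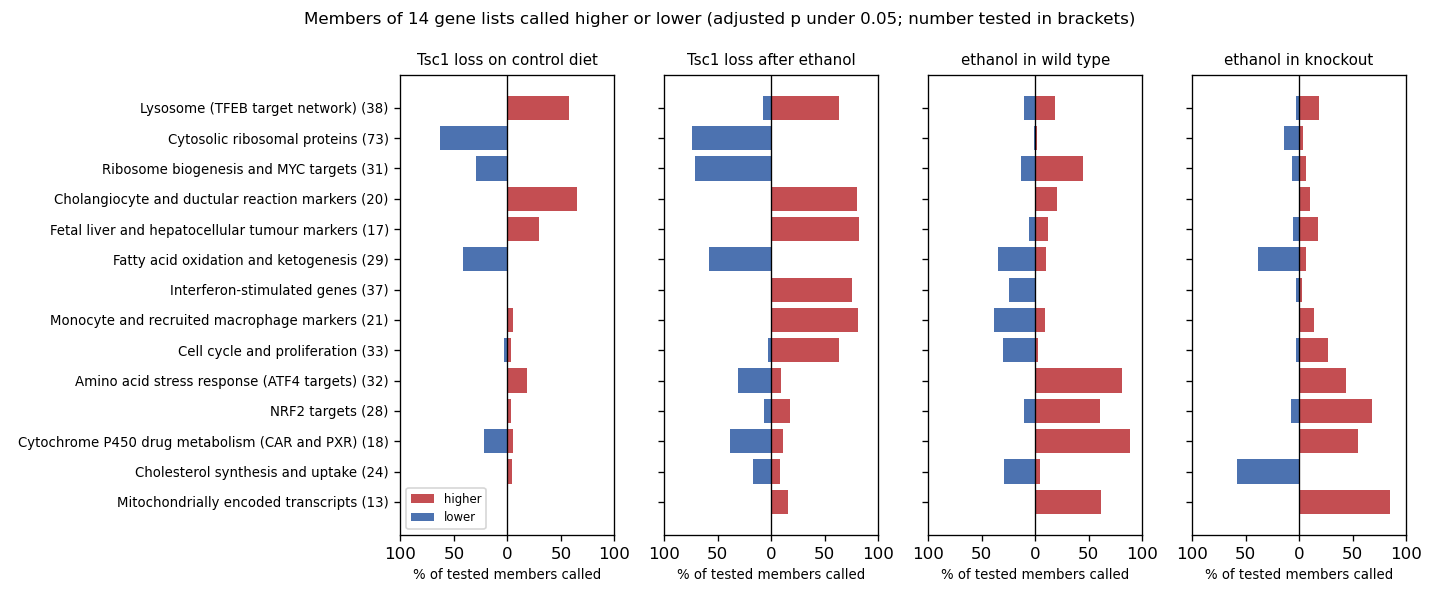
Share of the tested members of 14 gene lists called higher (right) or lower (left) at an adjusted p under 0.05 in each pairwise contrast, in percent, with the number tested in brackets. Tsc1 loss raised 22 and 24 of 38 TFEB targets on the 2 diets, and ethanol raised 17 and 19 of 28 NRF2 targets in wild type and knockout.

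In wild-type mice ethanol changed 4811 genes, 2525 upward and 2286 downward. The largest rise was in Cyp2b10, a drug-metabolising P450 (chromosome 7, 25897620 to 25926624, plus strand), from 2.64 ± 3.35 to 1071 ± 254.3 CPM (SD, n = 4), at 8.66 ± 0.97 log2 (SE, adjusted p = 2.69e-05). The metallothionein gene Mt2 rose by 6.92 ± 1.05, the cell cycle inhibitor gene Cdkn1a by 6.37 ± 0.54 and the acute-phase gene Orm3 by 6.07 ± 0.47. Atf3, Lcn2, Slc34a2 and Dusp8 rose by 5.34 to 5.59 log2, and without wild-type ethanol library 4 the value of Lcn2 was 3.65. Hsd3b5 (chromosome 3, 98618634 to 98630252, minus strand) fell from 324.5 ± 52.8 to 5.57 ± 3.06 CPM, and Ces4a, Mup21, Slc22a28, Adgrv1, Ugt2b38, Keg1 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell, at -4.85 to -3.46 log2. The authors' deposited table had 5174 genes with an adjusted p-value under 0.05 for this comparison, and DESeq2 run on the same counts called 5070.

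Stress and detoxification genes were among the rises. Of 32 ATF4 targets 26 rose and 0 fell (26 and 0 adjusted over the list alone, median 1.53 log2; camera adjusted p = 1.06e-10, or 0.520 with an estimated correlation). Ddit4 (chromosome 10, 59949669 to 59951834, minus strand) rose from 4.26 ± 0.601 to 159.6 ± 45 CPM (SD, n = 4), Sesn2 by 2.71 log2, the transcription factor gene Cebpb by 1.27 and the amino acid transporter gene Slc3a2 by 1.40, while Aars was at 0.25 ± 0.18 (adjusted p = 0.295). Of 28 targets of NRF2, the regulator of antioxidant defence, 17 rose and 3 fell (17 and 3 over the list alone, median 1.90; adjusted p = 5.21e-07, or 0.627 with an estimated correlation). The quinone reductase gene Nqo1 (chromosome 8, 107388225 to 107403206, minus strand) rose 6.33-fold, Gstm1 by 2.59 and Gsta2 by 3.52 log2, and Gclc, an enzyme of glutathione synthesis, was at -0.22 ± 0.32 (adjusted p = 0.618), and at 0.02 without wild-type control library 2. Of 18 drug-metabolising P450 genes and partners 16 rose and 0 fell (16 and 0 over the list alone; adjusted p = 6.15e-07, or 0.520 with an estimated correlation), with Por up by 1.54 and Cyp2c55 by 3.33, and the receptor gene Nr1i3 at -0.60 ± 0.38 (adjusted p = 0.238), called without wild-type ethanol library 3 (-1.02).

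Of 20 immediate early and stress genes 11 rose and 3 fell in wild type (11 and 3 adjusted over the list alone; camera adjusted p = 6.26e-04, or 0.794 with an estimated correlation), with Klf2 up by 1.81 and Klf6 by 3.19 log2. Of 23 p53 targets and growth arrest genes 6 rose and 1 fell (6 and 1 over the list alone; adjusted p = 0.0223, or 0.851 with an estimated correlation). Cdkn1a (chromosome 17, 29090976 to 29100727, plus strand) rose from 1.98 ± 0.977 to 165.7 ± 56.8 CPM (SD, n = 4) and Btg2 by 4.07 log2. Of 28 acute-phase genes 11 rose and 2 fell (13 and 2 over the list alone; adjusted p = 0.0164, or 0.895 with an estimated correlation), with Mt1 up by 4.38 log2 and the fibrinogen gene Fga at 1.12 ± 0.45 (adjusted p = 0.0664), called without wild-type ethanol library 1 (1.33) or 3 (1.37) or knockout control library 3 (1.12). The acute-phase score was 2.33 in wild-type ethanol library 4 and at most 0.83 in the other 3, and the list's call was lost without library 4 (median 0.392 log2 against 1.165 with all, adjusted p = 0.193). Of 33 cell cycle genes 10 fell and 1 rose (13 and 1 over the list alone; adjusted p = 0.00661, or 0.851 with an estimated correlation), with Mcm5 at -1.74 and Tk1 at -1.61.

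Lipid genes moved in opposite directions in wild type. Of 12 lipid droplet proteins 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00661, or 0.794 with an estimated correlation). Cidec (chromosome 6, 113424634 to 113435760, minus strand) rose 26.6-fold, from 4.49 ± 0.234 to 119.7 ± 67.6 CPM (SD, n = 4), Hilpda by 2.20 and Plin4 by 2.45 log2. Of 24 genes of cholesterol synthesis and uptake 7 fell and 1 rose (7 and 1 over the list alone; adjusted p = 0.0177, or 0.895 with an estimated correlation). Insig1, a brake on sterol synthesis (chromosome 5, 28071363 to 28078662, plus strand), fell from 282.7 ± 147 to 57.6 ± 11.4 CPM. The call of this list (median -0.432 log2) was lost without wild-type control library 4 (-0.211, adjusted p = 0.122) or wild-type ethanol library 3 (-0.339, adjusted p = 0.0816). Of 13 mitochondrially encoded transcripts 8 rose and 0 fell (8 and 0 over the list alone; adjusted p = 0.00181, or 0.851 with an estimated correlation), mt-Rnr2 by 1.08 and mt-Nd1 by 0.92, beside the higher mitochondrial share of counts given above.

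Immune cell markers fell in wild type after ethanol while endothelial markers rose. Of 16 lymphocyte markers 8 fell and 0 rose (10 and 0 adjusted over the list alone, median -1.19 log2; camera adjusted p = 5.45e-04, or 0.794 with an estimated correlation), with Cd4 at -2.49 ± 0.39, the immunoglobulin gene Ighm at -1.87 ± 0.36 and Cd74 at -0.72 ± 0.34 (adjusted p = 0.118), called without knockout ethanol library 2 (-0.73) and by voom (adjusted p = 0.0249). Of 14 Kupffer cell markers 7 fell and 0 rose (8 and 1 over the list alone; adjusted p = 0.00661, or 0.851 with an estimated correlation), with Adgre1 at -1.79 and Clec4f at -0.95. Of 21 monocyte and macrophage markers 8 fell and 2 rose (10 and 2 over the list alone; adjusted p = 0.0396, or 0.895 with an estimated correlation), Ccr2 (-1.94) and Lyz2 (-1.39) among the falls. Of 37 interferon-stimulated genes 9 fell and 0 rose (9 and 0 over the list alone; adjusted p = 7.32e-05, or 0.895 with an estimated correlation), with Oas3 at -1.88, Psmb8 at -0.86 and Ifi27l2a at -1.48, and Stat2 at -0.72 ± 0.29 (adjusted p = 0.0633), called without knockout control library 1 or 3 or knockout ethanol library 1 (-0.72 each), by DESeq2 and by voom (adjusted p = 0.0366 and 0.0228). Of 21 sinusoidal endothelial markers 8 rose and 2 fell (8 and 2 over the list alone; adjusted p = 0.00767, or 0.895 with an estimated correlation), Lyve1 by 2.61 and Bmp2 by 1.73. The monocyte call (median -1.046 log2) was lost without wild-type control library 2 (-0.652, adjusted p = 0.177) or wild-type ethanol library 3 (-0.979, adjusted p = 0.0766). With the stricter filter it was lost at the same median (adjusted p = 0.0739).

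Sex-biased liver genes shifted. Of 24 male-biased genes 9 fell and 0 rose in wild type (13 and 1 adjusted over the list alone, median -1.30 log2; camera adjusted p = 1.03e-04, or 0.851 with an estimated correlation), with Hsd3b5 at -5.87 ± 0.60 and Ugt2b38 at -3.66 ± 0.46. Of 15 female-biased genes 6 rose and 0 fell (9 and 0 over the list alone; adjusted p = 0.00943, or 0.851 with an estimated correlation), the sulfotransferase gene Sult1e1 by 4.88 ± 0.58. In the knockout 9 of 24 male-biased genes fell and 0 rose (16 and 0 over the list alone; adjusted p = 2.28e-12, or 0.636 with an estimated correlation), with Hsd3b5 at -7.72 ± 0.77 and Nudt7 at -2.32 ± 0.36, and 9 of 15 female-biased genes rose and 0 fell (13 and 0 over the list alone; adjusted p = 1.48e-08, or 0.176 with an estimated correlation), Cyp2b9 by 6.92 ± 0.94 and Cyp17a1 by 2.62 ± 0.47. Of the male-biased falls, DESeq2 called 10 in wild type and 13 in the knockout, and voom 14 and 17. The male-biased score was -5.52 in knockout ethanol library 2 and -2.43 to -1.30 in the other 3.

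In the knockout ethanol changed 2024 genes, 1004 upward and 1020 downward. Cyp2a4 and Cyp2b9, female-biased P450 genes, rose by 7.03 ± 1.28 and 6.92 ± 0.94 log2 (SE, adjusted p = 0.00336 and 6.35e-04), with Cyp2a4 at 4.55 without knockout ethanol library 2, and Cyp2b10 by 6.59 ± 0.88, from 9.14 ± 9.79 to 880.9 ± 311.4 CPM (SD, n = 4). Cyp2a22, Gstm3, Abcc4 and Orm3 rose by 3.72 to 4.08 log2. The cystine transporter gene Slc7a11 had a fitted rise of 5.26 ± 1.51, which was 1.24 without knockout ethanol library 2 (adjusted p = 0.406). Its call was lost too without wild-type control library 2 (5.26) or knockout control library 1 (5.09), 2 (5.29), 3 (5.24) or 4 (5.43), with voom (1.80, adjusted p = 0.147), the replicate block (3.88, adjusted p = 0.115) and no filter (5.23, adjusted p = 0.0897). Hsd3b5 fell most, to 0.287 ± 0.495 CPM, and Tbx3os1, Ces4a, Adgrv1, Ugt2b38, Slco1a1, Fabp5 and Mup21 fell, at -3.84 to -2.68 log2. Tbx3os1 is an antisense transcript, and the call of Slco1a1 was lost without knockout ethanol library 3 (-2.63) or 4 (-2.45), with no filter (adjusted p = 0.0508) and with only the 2 groups compared (0.0825), where that of Mup21 was lost too (0.0524). The authors' deposited table had 2507 genes with an adjusted p-value under 0.05 here, and DESeq2 run on the same counts called 2517.

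Of 28 NRF2 targets 19 rose and 2 fell in the knockout (21 and 3 adjusted over the list alone, median 1.82 log2; camera adjusted p = 2.38e-13, or 0.176 with an estimated correlation), with Srxn1 up by 2.15 and Gstm1 by 2.24. Nqo1 rose from 4.09 ± 0.627 to 21.3 ± 5.87 CPM (SD, n = 4), and Gclc was at 0.84 ± 0.32 (adjusted p = 0.0907). Of 18 drug-metabolising P450 genes and partners 10 rose and 0 fell (11 and 0 over the list alone; adjusted p = 1.07e-06, or 0.392 with an estimated correlation), with Cyp2c29 up by 2.29 and Cyp2c50 at 0.78 ± 0.31 (adjusted p = 0.101). Of 32 ATF4 targets 14 rose and 0 fell (17 and 0 over the list alone, median 0.57; adjusted p = 1.36e-05, or 0.636 with an estimated correlation), with Slc3a2 up by 1.62, Ddit4 by 1.39 and Ddit3 by 1.79. Of 24 genes of cholesterol synthesis and uptake 14 fell and 0 rose (18 and 0 over the list alone, median -0.92; adjusted p = 1.12e-08, or 0.636 with an estimated correlation), with Insig1 at -1.67, Fdps at -1.66 and Lss at -1.16, and Hmgcs1, the enzyme that forms the precursor of mevalonate, at -1.34 ± 0.44 (adjusted p = 0.0562). Hmgcs1 was called without wild-type control library 2 (-1.35) or 4 (-1.33) or knockout ethanol library 4 (-1.63). The call of Lss was lost without knockout control library 4 (-0.88) or knockout ethanol library 3 (-1.02), and with no filter (adjusted p = 0.0607). DESeq2 and voom called Hmgcs1 (0.0392 and 0.0145) and Gclc (0.0378 and 0.0449), and voom called Cyp2c50 (0.033).

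Of 29 fatty acid oxidation genes 11 fell and 2 rose in the knockout (13 and 5 adjusted over the list alone; camera adjusted p = 0.00450, or 0.728 with an estimated correlation), with Fabp1 at -1.69 ± 0.27, Acaa1a at -0.87 ± 0.14 and the thioesterase gene Acot2 up by 2.34 ± 0.40. Of 13 mitochondrially encoded transcripts 11 rose and 0 fell (13 and 0 over the list alone; adjusted p = 6.16e-07, or 0.636 with an estimated correlation), with mt-Nd6 up by 0.79 and mt-Atp6 by 0.83. Of 21 periportal hepatocyte genes 8 rose and 0 fell (8 and 0 over the list alone; adjusted p = 4.25e-04, or 0.636 with an estimated correlation), the urea cycle genes Cps1 and Arg1 by 0.85 and 0.79, and Alb was at 0.49 ± 0.22 (adjusted p = 0.143). Of 21 endothelial markers 8 rose and 1 fell (11 and 1 over the list alone; adjusted p = 0.00110, or 0.728 with an estimated correlation), Lyve1 by 2.73 and Pecam1 by 0.90. Of 33 cell cycle genes 9 rose and 1 fell (11 and 1 over the list alone; adjusted p = 0.00226, or 0.677 with an estimated correlation), Mki67 by 1.34 and Cdc20 by 2.03.

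Several of these knockout calls were lost in fits with fewer libraries, some with smaller values and some without. The fatty acid oxidation list had a median of -0.307 log2, and of -0.200 without knockout control library 2. It lost its call without knockout ethanol library 2 (-0.197, adjusted p = 0.0908) and, at a median of -0.324, without knockout ethanol libraries 1 and 2 (adjusted p = 0.270). The median of the cell cycle list was 0.548, 0.314 without knockout ethanol library 2 and 0.247 without both, where its call was lost (adjusted p = 0.169). Mki67 lost its call without library 2 (0.84, adjusted p = 0.0742) and without both (0.65), as did Cdc20 without both (1.04). Fdps (-1.68) and Lss (-1.28) lost theirs without both at values no smaller than with all libraries. The call of Mki67 was also lost without knockout control library 1 (1.35), 2 (1.32) or 3 (1.23), and that of mt-Atp6 without knockout ethanol library 4 (0.60). Alb was called by voom (0.55, adjusted p = 0.027) and without knockout ethanol library 2 (0.66) and Cyp2c50 likewise (1.04). The count of 2024 genes fell to 1326, 1114 and 1296 without knockout control library 1, 2 or 4, and to 1310 without knockout ethanol library 4.

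The ethanol response differed between genotypes in 259 genes by the interaction test, 75 with a positive and 184 with a negative interaction. In 130 of these the response had the same sign and was smaller in the knockout, in 128 the fitted sign was opposite and in 1 it was larger. Of the 130, 95 were called in wild type alone and 35 in both genotypes. Of the 128, 96 were called in wild type alone, 19 in the knockout alone and 13 in both, so most had no called response in the knockout. The smallest p belonged to Ddit4, which rose 37.4-fold with ethanol in wild type and 2.62-fold in the knockout, from 20.4 ± 5.78 to 53.5 ± 21.8 CPM (SD, n = 4), an interaction of -3.84 ± 0.41 log2 (SE, adjusted p = 9.18e-04). The phospholipase gene Pla2g12a (-1.57 ± 0.18) and Arhgef3 (-1.10 ± 0.13) had the same adjusted p. Msrb3, Aebp2, Ripk4, Cep85l and the syndecan gene Sdc4 had interactions of -1.87 to -1.16 log2. Leaving out 1 library moved the count more than 1.5 times in 11 of 16 fits, to 53, 79 and 56 without wild-type control library 1, 3 or 4, to 150, 495 and 139 without wild-type ethanol library 1, 3 or 4, to 88, 126, 119 and 85 without knockout control library 1, 2, 3 or 4, and to 156 without knockout ethanol library 4. Without knockout ethanol libraries 1 and 2 it was 116, of which 79 were among the 259.

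Of 32 ATF4 targets 5 had a called interaction, all negative (10 adjusted over the list alone, median -0.46 log2; camera adjusted p = 6.53e-06, or 0.966 with an estimated correlation). DESeq2 called 8 and voom 9. The median was -0.72 without wild-type control library 2, -0.30 without wild-type ethanol library 4, -0.78 without knockout ethanol library 2 and -0.97 without knockout ethanol libraries 1 and 2. Gdf15 (chromosome 8, 70629393 to 70632456, minus strand) had an interaction of -4.70 ± 0.88 (adjusted p = 0.0235). It stood at 3.89 ± 1.35 and 110.7 ± 47.0 CPM in wild type on control diet and after ethanol, and at 48.1 ± 39.5 and 52.6 ± 30.5 CPM in the knockout (SD, n = 4). Cebpb (-1.55 ± 0.25) and the amino acid transporter gene Slc7a5 (-2.18 ± 0.48) also had negative interactions. Cdkn1a rose 82.7-fold in wild type and 8.18-fold in the knockout. Of 20 immediate early genes 2 had a negative and 1 a positive interaction (10 and 3 over the list alone; adjusted p = 0.00727, or 0.966 with an estimated correlation), Btg2 at -3.60 ± 0.66 and Ier2 at -1.39 ± 0.30, where DESeq2 called 6 negative ones and voom 4. Of 12 lipid droplet proteins 2 had a negative interaction and 0 a positive one (4 and 0 over the list alone; adjusted p = 0.0125, or 0.966 with an estimated correlation), Hilpda at -2.03 ± 0.40 and Plin4 at -2.30 ± 0.46. Cidec was at -1.91 ± 0.58 (adjusted p = 0.101). The call of the droplet list (median -0.466 log2) was lost without knockout ethanol library 2 (-0.383, adjusted p = 0.0586) and without libraries 1 and 2 of that group (-0.289, adjusted p = 0.144). That of the immediate early list (median -1.233) was lost without both too (-1.095, adjusted p = 0.0646). Calls of single genes were lost without wild-type control library 1, 3 or 4 for Gdf15 (-4.71 to -4.48) and Btg2 (-3.57 to -3.47), and without wild-type control library 1 or 3 or knockout control library 4 for Hilpda (-2.04 to -1.88). That of Plin4 was lost without wild-type control library 1 or 4 or knockout control library 1, 3 or 4 (-2.31 to -2.15). Slc7a5 (-2.27 to -2.04) and Ier2 (-1.51 to -1.25) lost theirs without wild-type control library 1, 3 or 4, wild-type ethanol library 1 or any 1 knockout control library, and also without knockout ethanol library 3 or 4 for Slc7a5 and 1, 2 or 3 for Ier2. With no filter the calls of Slc7a5 (adjusted p = 0.0664), Plin4 (0.0661) and Ier2 (0.0613) were lost, and with the replicate block that of Slc7a5 (0.0567).

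Immune and cell cycle lists had positive interactions by camera, with few single genes called. In the interferon list edgeR called 1 of 37, DESeq2 6 and voom 1, with Oas3 at 3.00 ± 0.71 (4 adjusted over the list alone, median 1.61 log2; adjusted p = 6.79e-10, or 0.966 with an estimated correlation), and Iigp1 was at 0.56 ± 0.37 (adjusted p = 0.427). In the monocyte list edgeR called 1 of 21, DESeq2 6 and voom 2, with Lyz2 at 1.97 ± 0.43 (9 over the list alone; adjusted p = 2.31e-05, or 0.966 with an estimated correlation), and Csf1r was at 1.30 ± 0.34 (adjusted p = 0.0588), called without knockout ethanol library 3 (1.46). In the Kupffer cell list edgeR called 1 of 14, DESeq2 2 and voom 0 (6 at an unadjusted p under 0.05), with Vsig4 at 1.27 ± 0.29 (6 over the list alone; adjusted p = 0.00268, or 0.966 with an estimated correlation). In the cell cycle list edgeR called 0 of 33 (11 over the list alone; adjusted p = 6.79e-10, or 0.616 with an estimated correlation). At an unadjusted p under 0.05 there were 18, all positive, and DESeq2 called 6 and voom 0, with Ccnd1 at 1.18 ± 0.39 (adjusted p = 0.118) and Pcna at 0.41 ± 0.17 (adjusted p = 0.197). The median of the interferon list was 0.66 without knockout ethanol library 1 and 0.44 without libraries 1 and 2 of that group, and that of the cell cycle list 0.66 without both. The call of Oas3 was lost without any 1 of the 8 control-diet libraries, wild-type ethanol library 1 or 4 or knockout ethanol library 1 or 2 (2.41 to 3.18), and that of Lyz2 without any 1 control-diet library or wild-type ethanol library 1 or 4 (1.82 to 2.07). Vsig4 lost its call without any 1 wild-type control library, wild-type ethanol library 1 or 4, knockout control library 1, 3 or 4 or knockout ethanol library 1 (1.14 to 1.35). Voom did not call Oas3 (adjusted p = 0.0667) or Vsig4 (0.0714), the replicate block lost Oas3 (0.0523) and the fit with no filter Lyz2 (0.0782). DESeq2 called Csf1r (0.00783) and Ccnd1 (0.0418), and voom called Csf1r (0.0455).

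**Figure D4:**
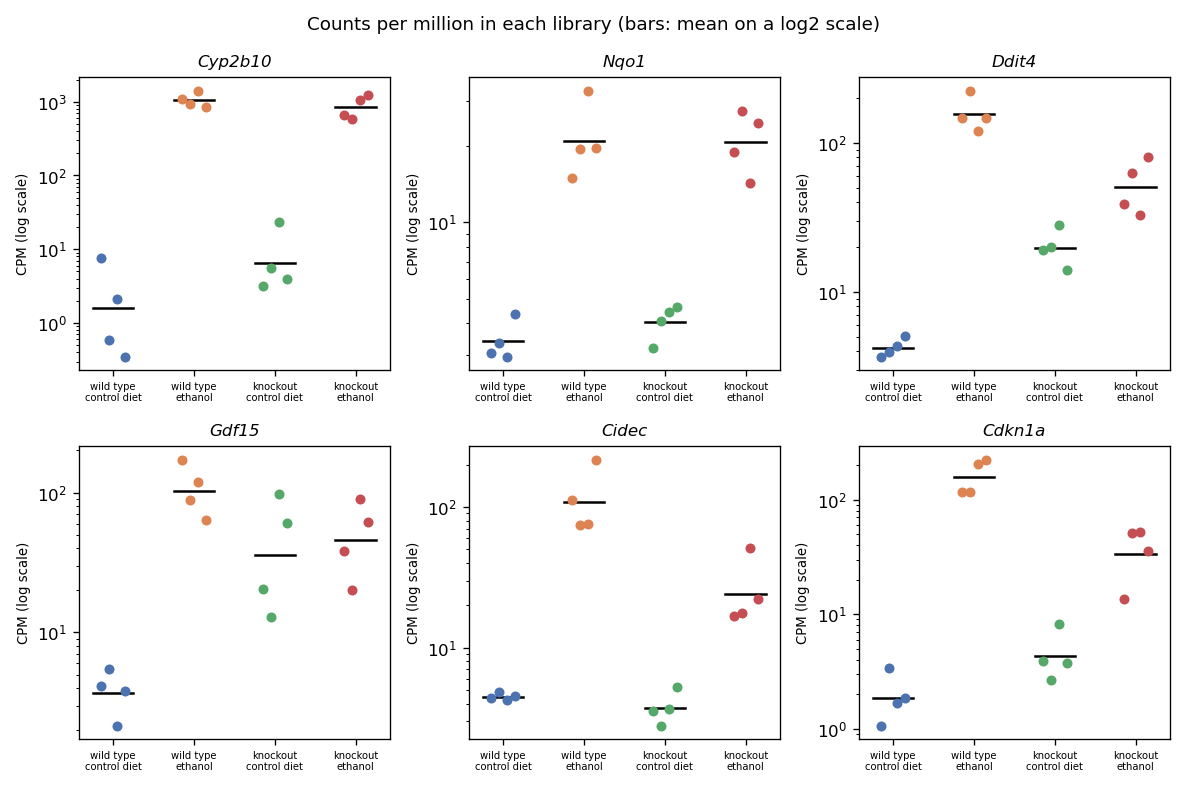
Cyp2b10, Nqo1, Ddit4, Gdf15, Cidec and Cdkn1a in CPM on a log scale in each of the 16 libraries by group, with a bar at the mean of log2 values. Nqo1 reaches 14.9 to 33.1 CPM in wild type and 14.3 to 27.5 in the knockout after ethanol, while Cdkn1a reaches 116.6 to 224.9 and 13.5 to 52.5.

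Tsc1 loss was compared between the diets, and 1353 genes were called in the same direction on both, 826 upward and 527 downward, where independent lists of these sizes would share 207.9 and 134.65. In opposite directions 10 were called (340.78 for independent lists). The fold changes on the 2 diets, which share no library, correlated across genes with Pearson's r = 0.666 and Spearman's rho = 0.569, as a description, since genes are not independent replicates. For ethanol in the 2 genotypes 644 genes rose and 665 fell in both (176.71 and 162.53 for independent lists) and 13 went opposite ways (339.51), with r = 0.610 and rho = 0.546. Over the genes called in wild type the median ratio of the knockout to the wild-type fold, on the log2 scale, was 0.436. The overlap for Tsc1 loss fell to 890 and 885 without knockout control library 1 or 4, and that for ethanol to 801 without knockout control library 2.

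**Figure D5:**
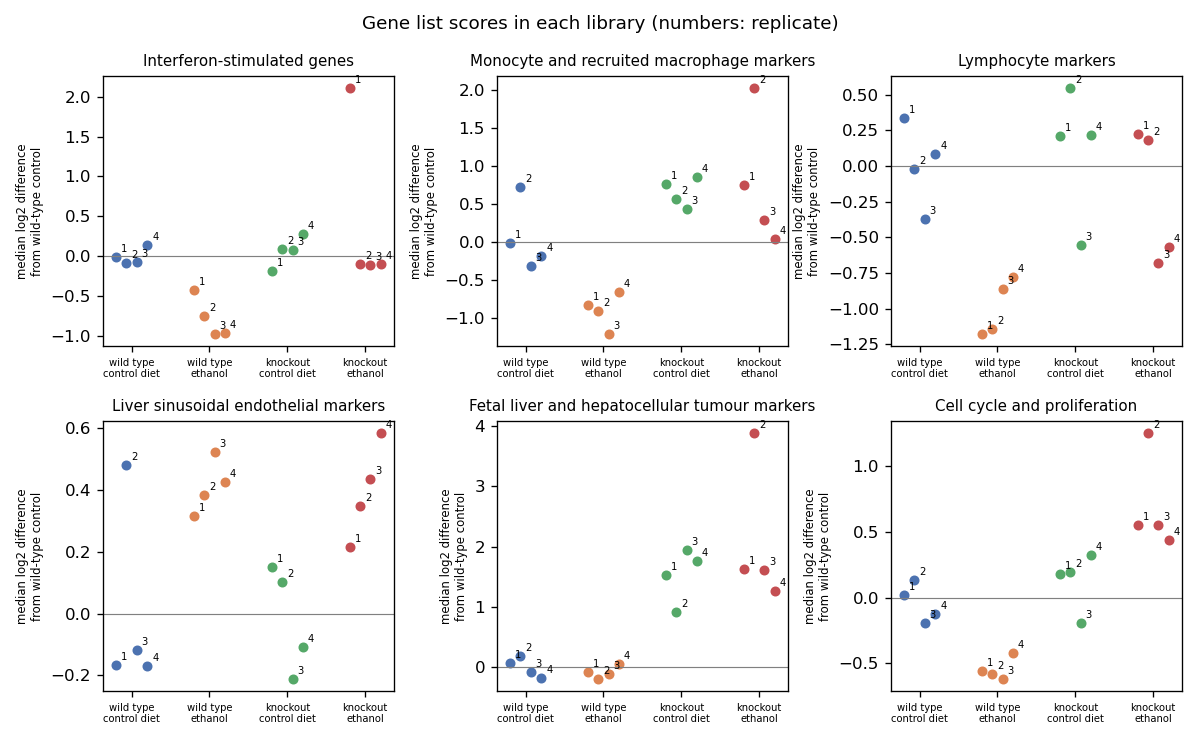
Scores of 6 gene lists in each library, as the median log2 difference of the members from wild-type controls, with replicate numbers beside the points. Knockout ethanol library 1 stands at 2.11 for interferon-stimulated genes, and knockout ethanol library 2 at 3.88 for fetal and tumour markers, against at most 1.63 in the other 3 of its group.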

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

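The tests of a bias against short transcripts, of pseudogenes, of the knockout libraries that stood apart, of a wrong label, of a lower share of hepatocytes, of an earlier move of the same genes by Tsc1 loss and of selection by the wild-type fold were chosen only after the results they bear on were seen. Each of 220 groups of 4 values, of single genes or list scores, was searched for a library far from the other 3. There were 17 such groups, where chance gives about 11.

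Among single genes, H19 stood at 675.2 CPM in knockout ethanol library 2 against 4.06 to 17.4 in the other 3, and at 0.1551 CPM in wild-type ethanol library 1 against 0 in the other 3, which is near the counting limit. Hsd3b5 stood at 1.024 CPM in knockout ethanol library 1 against 0 to 0.125. Cd68 stood at 9.006 CPM in wild-type control library 2 against 4.01 to 4.51, Cyp2b10 at 23.75 CPM in knockout control library 3 against 3.21 to 5.62, and Cidec at 51.35 CPM in knockout ethanol library 3 against 16.7 to 22.2.

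Among list scores, given as log2 differences from wild-type controls, knockout ethanol library 1 had 2.105 for interferon-stimulated genes against -0.109 to -0.101 in the other 3. Knockout ethanol library 2 had 3.875 for fetal and tumour markers against 1.258 to 1.631, 1.253 for cell cycle genes against 0.441 to 0.551, and 1.454 for stellate cell markers against 0.164 to 0.333. Knockout control library 3 had -0.158 for ribosome biogenesis against -0.373 to -0.342, and 0.073 for mTORC1 components against 0.186 to 0.208. Knockout control library 4 had 0.687 for chemokines against 0.300 to 0.346 and 0.717 for cholesterol genes against -0.023 to 0.043. Wild-type control library 2 had 0.482 for endothelial markers against -0.170 to -0.117, wild-type control library 4 had -0.041 for complement genes against -0.002 in each of the other 3, and wild-type ethanol library 3 had -0.988 for cholesterol genes against -0.378 to -0.296.

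The ethanol response differed between the genotypes by the interaction test in 23 of 200 named genes. Il1r1 rose in wild type (3.53 log2) and was at -0.72 in the knockout, an interaction of -4.257. The negative interactions of Gdf15 (-4.695), Ddit4 (-3.835), Btg2 (-3.598), Cdkn1a (-3.339), Plin4 (-2.299), Slc7a5 (-2.182) and Hilpda (-2.028) belong to genes described above. Others were those of Ciart (-2.143), Cep85l (-1.867), Sdc4 (-1.687), Nfil3 (-1.572), Pla2g12a (-1.567), Cebpb (-1.546), Aebp2 (-1.442), Ier2 (-1.385), Msrb3 (-1.328), Ripk4 (-1.16) and Arhgef3 (-1.102). Oas3 (2.995), Lyz2 (1.969) and Vsig4 (1.269) fell in wild type and had values of 1.12, 0.58 and 0.25 log2 in the knockout. Etnppl (2.104) fell in wild type (-0.92) and rose in the knockout (1.19). The interaction call of Cdkn1a was lost without wild-type control library 1 (-3.12), 3 (-3.25) or 4 (-3.30), wild-type ethanol library 4 (-3.15) or knockout control library 1 (-3.42) or 3 (-2.90). That of Nfil3 was lost without wild-type control library 1 (-1.46) or 4 (-1.63), wild-type ethanol library 1 (-1.48) or knockout control library 1 (-1.55), 2 (-1.52) or 3 (-1.57). Other calls among the 23 lost without a library are given above. Without knockout ethanol libraries 1 and 2, 10 of the 23 were no longer called, Il1r1 (-4.23), Nfil3 (-1.67), Gdf15 (-4.16), Btg2 (-3.33), Plin4 (-2.17), Slc7a5 (-2.46), Hilpda (-1.75), Ier2 (-1.12), Oas3 (1.86) and Vsig4 (0.89).

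The median fall of ribosomal protein transcripts with Tsc1 loss was -0.53 log2 on control diet and -0.67 after ethanol (library-median gaps -0.637, SE 0.091, and -0.801, SE 0.121). A bias against short transcripts was argued against by 314 genes matched on level and on the length of their shortest principal annotated transcript (median 815 bases, 751 for the ribosomal genes), whose medians were -0.075 and -0.014. The summed CPM of 275 pseudogenes, taken by symbol, also fell, by a change of -2.85% of the parents' loss on control diet and -3.09% after ethanol. The lost reads were therefore not counted in these 275 rows. Whether reads were lost to pseudogenes is not decided, since those under other symbols were not summed and multiply mapped reads may have been counted nowhere. An effect of genotype stays open as a hypothesis, as does a change in the mix of cells, untested for these genes.

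Over the genes called in wild type the knockout's ethanol fold was a median 0.436 of the wild-type fold on the log2 scale. The knockout libraries that stood apart were argued against as the cause, since the ratio was 0.471 without library 1, 0.429 without library 2 and 0.48 without both, below a bound of 0.8 that was set after the 0.436 and before these 3 ratios were seen. Selection by the wild-type fold was argued against as the whole cause, since over the genes called in the knockout the ratio the other way round was 0.894. An earlier move by Tsc1 loss was argued against on average but stays open for Ddit4, Gdf15 and other ATF4 targets it raised. The wild-type controls were divided between the contrasts in 6 ways. The slope of the Tsc1-loss fold on the ethanol fold then had a median of 0.089 (0.053 to 0.134). A slope of 0.267 would fill 50% of the missing response. A difference in alcohol breakdown may also give such a ratio and stays open, with 1 of 10 genes of ethanol and acetaldehyde metabolism higher and 4 lower in the knockout after ethanol (tested below), and alcohol intake and timing were not tested.

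Knockout ethanol library 2 stood apart in fetal, cell cycle and monocyte genes. A wrong label was argued against by its genotype score of 2.176, where wild-type libraries reached 0.276, and by its ethanol score of 0.962, where control-diet libraries reached 0.32. A lower share of hepatocytes with the other cell types in unchanged proportion would raise those types alike. That case was argued against by a gap of 1.662 between monocyte markers (1.60 above the other 3 libraries) and endothelial markers (-0.06). The SE of this gap, 0.251, was taken over marker genes, not over libraries. A lower share with uneven gains of the other cell types could give such a gap and stays open. Cholangiocyte (1.41) and stellate (1.25) markers were also higher there, and Kupffer (0.43) and lymphocyte (0.39) markers less so. An animal or piece of tissue with more injury, regrowth or a tumour could give such a profile, and no label bears on it.

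For the counts of genes called, 1 of 35 splits of the libraries, the real one, gave as many in Tsc1 loss on control diet (1766, highest other 0), Tsc1 loss after ethanol (5551, highest other 78), ethanol in wild type (4811, highest other 9) and ethanol in knockout (2024, highest other 5). If the libraries are independent, a chance split can be excluded for each of these 4 counts at the 0.05 level. The labels do not say that they came from separate animals. Were libraries of a group from 1 animal, the splits would not test differences between animals. For the counts of lists called by camera in these 4 comparisons a chance split cannot be excluded. In the same order, 5 of 35 splits gave as many lists (17, highest other 24), 21 of 35 (17, highest other 31), 6 of 35 (18, highest other 21) and 27 of 35 (18, highest other 25). For the interaction 3 of 100 splits gave as many genes (259, highest other 458) and 84 of 100 as many lists (11, highest other 29). Those splits mix genotypes and diets within groups, so that the effects of each enter the spread, and they do not decide whether the interaction counts arose by chance.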

How the results depend on the processing

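The fit without knockout ethanol libraries 1 and 2 was chosen only after the data were seen, and the other alternatives before. The counts of genes for Tsc1 loss after ethanol and for ethanol in wild type stayed within 1.5 times under every alternative, at 3964 to 5829 and 3890 to 5316. With voom, 3603 genes were called for Tsc1 loss on control diet, 3302 for ethanol in knockout, 545 for the interaction and 2103 in the same direction for Tsc1 loss on both diets. DESeq2 called 731 interaction genes, and the fit without that pair 116. With no filter 17 lists were called for the interaction. With an estimated correlation 0 lists were called in each contrast, with unadjusted counts given above. Fry called 11 for Tsc1 loss on control diet, 11 for ethanol in knockout and 0 for interaction (5 at an unadjusted p under 0.05). The fall of Tsc1 after ethanol missed the threshold with no filter (-0.354), voom (-0.396), the replicate block (-0.365), only the 2 groups compared (-0.345) and without the pair (-0.271), and its ethanol fall in the knockout passed with voom (-0.395). Leaving out 1 library gave 1091 to 2167 genes for Tsc1 loss on control diet, 1114 to 2279 for ethanol in knockout, 53 to 495 for the interaction, 885 to 1473 shared by Tsc1 loss on both diets and 801 to 1422 shared by ethanol in both genotypes. It gave Tsc1 falls of -0.655 to -0.464 on control diet and -0.427 to -0.281 after ethanol. In wild type after ethanol Gclc ran from -0.514 to 0.019, Cbs from -0.202 to 0.055, Kng1 from -0.03 to 0.15 and Npm1 from -0.261 to 0.01, none of them called in these 16 fits. The stellate cell list after ethanol ran from -0.104 (without knockout ethanol library 2) to 0.705 by Tsc1 loss and was -0.116 without the pair, where the clock list had a median of 0.071 for ethanol in the knockout, and neither list was called. The cause of these shifts was not tested, except that fits without libraries have less power. The replicate block called 1778, 5532, 4877, 2002 and 255 genes. A pairing by number is not excluded. Same-numbered deviations correlated at -0.146 to 0.414 (median 0.018, other pairs -0.008), over 0.1 in 7 of 24 pairs. Of 16 libraries 7 correlated best with their own number. Among 258 named gene results, 18 lost their call without some 1 library, and 8 of 76 lists did. So did the interactions of Cdkn1a and Nfil3, which are not among these results. Depth limits genes of few counts, such as H19 in wild type.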

Other observations

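Both tests of glucocorticoid receptor targets were chosen only after the results were seen, among them the values of Pdk4 and Per1, which are in that list. The lists in the next 2 paragraphs were written before the data were examined.

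In wild type after ethanol, genes of methionine and glutathione metabolism moved both ways. Of 25 tested 10 rose and 3 fell (10 and 3 over the list alone; camera adjusted p = 0.102, or 0.851 with an estimated correlation, and 0.0492 without wild-type ethanol library 1). Mat1a, which makes the methyl donor of the liver, rose from 3474 ± 578.1 to 10050 ± 2014 CPM (SD, n = 4), at 1.53 log2 (adjusted p = 1.5e-05), and Mat2a rose by 0.92, while the methionine synthase gene Mtr fell (-0.98). In the knockout 7 rose and 2 fell (9 and 2 over the list alone; camera adjusted p = 0.0544, or 0.677 with an estimated correlation), Mat1a by 1.19 log2. That list passed without wild-type control library 2 (0.0476), wild-type ethanol library 2 (0.0454), 3 (0.0370) or 4 (0.0486), knockout control library 2 (0.0353) or 4 (0.0403), or knockout ethanol library 2 (0.0178). Of 29 complement and coagulation genes 12 fell and 4 rose in wild type (12 and 4 over the list alone; camera adjusted p = 0.0640, or 0.851 with an estimated correlation), with C9 at -1.28, F11 at -1.04 and Mbl2 at -0.96 log2. It passed without wild-type control library 4 (0.0484), wild-type ethanol library 4 (0.0338) or knockout ethanol library 1 (0.0488) or 2 (0.0345). In the knockout 8 fell and 0 rose (9 and 1 over the list alone; camera adjusted p = 0.133, or 0.728 with an estimated correlation, and 0.0422 without knockout ethanol library 4), with F11 at -1.22 and Mbl1 at -0.87. Of 10 genes of ethanol and acetaldehyde metabolism 3 fell and 0 rose in wild type (3 and 0 over the list alone; camera adjusted p = 0.248, or 0.913 with an estimated correlation), with Adh4 at -1.48 and Cyp2e1 at -0.31 (adjusted p = 0.401). Between the genotypes after ethanol 1 was higher in the knockout, Aldh1b1 at 1.95, and 4 were lower, Adh5 at -0.71 among them (1 and 4 over the list alone; camera adjusted p = 0.170, or 0.860 with an estimated correlation). Of 31 ribosome biogenesis and MYC target genes 14 rose and 4 fell (16 and 5 over the list alone; camera adjusted p = 0.0802, or 0.895 with an estimated correlation, and 0.0474 and 0.0276 without wild-type control library 3 or wild-type ethanol library 2). Myc rose by 2.71 and Odc1 by 1.20 log2, and Dkc1 was at -0.81. With no filter the methionine list passed in wild type (0.0218) and in the knockout (0.0148, and 0.0462 with the stricter filter), and in wild type so did the complement (0.0245) and ribosome biogenesis lists (0.0145).

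Clock genes moved both ways as well. Of 18 tested 7 rose and 5 fell in wild type (7 and 5 over the list alone; camera adjusted p = 0.805, or 0.975 with an estimated correlation), with Nfil3 up by 1.78 and Ciart by 1.65 log2, and Dbp at -2.12 and Tef at -0.76. In the knockout 1 rose and 5 fell (3 and 6 over the list alone; camera adjusted p = 0.464, or 0.728 with an estimated correlation), with Dbp at -1.64 and Tef at -0.66, where Nfil3 was at 0.21 (adjusted p = 0.578) and Ciart at -0.49 (adjusted p = 0.162). DESeq2 called 3 rises there and voom 4. The time of day of sampling is not in the labels. Between the genotypes after ethanol, 21 of 56 nuclear genes of oxidative phosphorylation were lower in the knockout and 1 higher (21 and 1 over the list alone; median -0.23 log2, and -0.15 without wild-type ethanol library 3; camera adjusted p = 0.00131, or 0.860 with an estimated correlation), with Ndufa9 at -0.50. Of 21 periportal genes 11 were higher and 5 lower (11 and 5 over the list alone; camera adjusted p = 0.122, or 0.818 with an estimated correlation, and 0.0111 without knockout ethanol library 2 and 0.0449 with no filter), with Etnppl at 2.30, Ctsc at 1.94 and Cdh1 at 1.54. Of 28 stellate cell and fibroblast markers 7 were higher and 5 lower (7 and 5 over the list alone; median 0.53, and -0.10 without knockout ethanol library 2; camera adjusted p = 0.755, or 0.970 with an estimated correlation), where DESeq2 called 9 higher and voom 2, with Ecm1 at -0.75, and at -0.49 without knockout ethanol libraries 1 and 2.

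A hypothesis is that ethanol in wild type came with a glucocorticoid response, since stress genes rose and lymphocyte markers fell, and that this response was smaller in the knockout. Of 14 targets of the glucocorticoid receptor 13 were tested. In wild type 10 rose and 0 fell after ethanol (10 and 1 over the list alone), with a median of 1.36 log2 (camera p = 2.144e-05, or 0.0147 with an estimated correlation). In the knockout 2 rose and 1 fell (3 and 1 over the list alone), with a median of 0.40 (camera p = 0.0760, or 0.258 with an estimated correlation). The interaction had a median of -1.18 (camera p = 4.489e-05, or 0.0181 with an estimated correlation). For single targets edgeR called 0 interactions, with 7 negative ones at an unadjusted p under 0.05, where DESeq2 called 2 and voom 4. Between the genotypes 7 of the 13 were lower in the knockout after ethanol (10 over the list alone, camera p = 2.871e-04, or 0.0317 with an estimated correlation), but 4 without knockout ethanol libraries 1 and 2. Without Pdk4 and Per1 the camera p was 1.971e-04 (0.0111 with an estimated correlation) in wild type and 8.041e-05 (0.00799) for the interaction.

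Sgk1, Zbtb16 and Klf9 rose by 3.22, 2.80 and 1.09 log2 in wild type, and were at 1.42, 0.55 and -0.10 in the knockout with adjusted p of 0.0703, 0.528 and 0.80. Other targets differed from these. Fkbp5 rose in both genotypes, by 2.27 in wild type and 1.57 in the knockout (interaction -0.70, adjusted p = 0.568). Tsc22d3 was at 0.68 in wild type (adjusted p = 0.13). Bcl6 was at -1.725 there (adjusted p = 0.0648), with an interaction of 1.41 (adjusted p = 0.444). The values of the tests with a preset correlation stayed under 0.05 in wild type and for the interaction without any 1 library, at no more than 7.082e-05 and 2.033e-04. In the knockout the value went under 0.05 without wild-type control library 2 (0.0486) or 3 (0.0439), knockout control library 1 (0.0101) or 2 (0.0302), or knockout ethanol library 1 (0.0334) or 2 (0.0215). Without knockout ethanol libraries 1 and 2 it was 0.00183 for the interaction with a preset and 0.0512 with an estimated correlation. The result of 2.144e-05 may also come from fasting or energy shortage, which raise Pdk4, Angptl4, Lpin1 and Klf9, or from a shift of the clock, of which Per1 is a part. No hormone level is in the labels, and the data were not able to separate these.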
